A study of Mus musculus with 18 samples.

How the data were processed

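The series profiled messenger RNA of mouse CD4+ T cells. Naive CD4+ T cells were sorted by flow cytometry from spleens of C57BL/6 mice, activated with antibodies to CD3 and CD28, and harvested on day 4, per the labels' protocols. In experiment 1 the cells came from mice with floxed Egln1, Egln2 and Egln3 and a Cd4Cre transgene (tKO) or from Cd4Cre controls (WT), and each genotype was cultured with 0, 0.2 or 2 ng/ml TGF-b. Cd4Cre is a recombinase expressed in developing T cells, and Egln1, Egln2 and Egln3 encode PHD2, PHD1 and PHD3, the oxygen-sensing prolyl hydroxylases that mark HIF proteins for degradation. In experiment 2, cells were cultured with 2 ng/ml TGF-b and either vehicle or 1 mM DMOG (dimethyloxalylglycine), a cell-permeable inhibitor of 2-oxoglutarate-dependent dioxygenases, PHD proteins among them. Experiment 1 has 6 groups of 2 libraries and experiment 2 has 2 groups of 3. The experiments were sequenced on different instruments and deposited as separate tables.

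Polyadenylated RNA was isolated with RNeasy columns and amplified with a SMARTer Ultra low input kit, per the labels' protocols. The kit amplifies full-length cDNA from little RNA and does not mark the strand, so reads of a gene and of an antisense partner cannot be told apart. The submitters' processing notes name Trimmomatic, TopHat, Cufflinks, Cuffdiff and the mm9 build; their versions and roles are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each library, per the file headers. No counts were used here, so no count model was fitted and no interval for counting error is given.

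Depth was compared from the low values. FPKM sums ran from 548974 to 856147 per library in experiment 1 and from 386382 to 443888 in experiment 2. Entries with low mean values, above 0 in the libraries compared, gave relative numbers of reads per FPKM. In experiment 1 these lay between 0.530 and 1.20, with the lowest in tKO at 0.2 ng/ml, replicate 2. In experiment 2 they lay between 0.809 and 1.31. Absolute depth is unknown. Each library had between 9560 and 10342 gene symbols at 1 FPKM or more. The 10 most abundant symbols took between 6.73% and 10.0% of the FPKM sum.

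The table of experiment 1 held 34309 entries, of which 8483 had no gene symbol, and that of experiment 2 held 23028. After 17 and 291 exact duplicates were dropped, FPKM values of entries with the same symbol were summed, which gave 22783 and 16639 symbols. Entries that join overlapping genes with a comma were kept under the joint name and are uncertain as to which gene the reads came from. Entries with no symbol took between 2.51% and 9.55% of the FPKM of a library of experiment 1 and were tested apart from the genes. Coordinates are those given with experiment 1, mm9, 1-based.

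Genes with a mean of at least 1 FPKM over the libraries of a table were tested on log2(FPKM + 1), which left 10354 genes in experiment 1 and 9884 in experiment 2. Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, a mean-variance trend and a spread shared by all libraries of the experiment. All adjusted p-values are limma's moderated tests with Benjamini-Hochberg adjustment over the genes of a comparison, two-sided, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The comparisons were tKO minus WT averaged over the 3 doses and at each dose, TGF-b at 0.2 and at 2 minus 0 ng/ml in each genotype, the difference of the 2 minus 0 ng/ml effect between the genotypes, and DMOG minus vehicle. The experiments were normalized separately, so tests were made only within a table. Fold changes of tKO at 2 ng/ml and of DMOG were correlated across genes with no library in common.

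A value of exactly 0 can be a failed estimate in these tables. Such values are given as listed at 0. Fold changes of genes with some libraries listed at 0 are uncertain, and the text says which genes these are.

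The 27 gene lists with 410 genes, the comparisons, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. The lists cover glycolysis, other HIF targets, the TCA cycle, oxidative phosphorylation, regulatory T cell, Th1, Th2, Th17 and cytotoxic genes, TGF-b response, naive and memory genes, cell cycle, checkpoint receptors, interferon-stimulated genes, ATF4 and amino acid genes, cholesterol synthesis, immediate early genes, p53 targets, ribosome biogenesis, and markers of T cells, B cells, myeloid cells, dendritic and MHC class II cells, CD8 T cells, NK cells, gamma-delta and NKT cells, and erythroid cells. The tables held 408 of the list genes in experiment 1 and 397 in experiment 2. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated per list.

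Genes were named by these parts of the rule: Egln1, Egln2, Egln3, Hif1a, Epas1 and Vhl; the 8 genes up and the 8 down with the largest change and no overlap between libraries in the 4 main comparisons, with a mean of at least 5 FPKM on the higher side; up to 4 members with the smallest p of each list described; a panel of 20 genes of T cell function and metabolism whose values may always be given; the 6 genes with the smallest p in the remaining contrasts; and the 10 genes with the largest change in the same direction, and the 6 in opposite directions, in tKO and with DMOG. Epas1 did not pass the expression filter in either table. Some genes that the rule names are not reported here.

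The alternatives were a pseudocount of 0.1 FPKM, no expression filter, a filter at 5 FPKM, quantile normalization, median centring, no variance trend, the replicate number as a block, the labelled series as a fixed or random factor, a fit of only the groups compared, the mean per labelled series, and each library or series left out in turn. The entry with the highest mean per symbol in place of the sum, the random series factor for the TGF-b contrasts and the covariance in place of r over regrouped libraries were chosen after seeing the data. The labels number the series WT1, WT2, tKO1 and tKO2 at every dose and do not say whether each is a single mouse; where libraries of a group share an origin, p-values measure only the spread between these samples, which may be technical. In tKO the deviations of same-numbered libraries from their group means correlated at 0.416, 0.127 and 0.110. Same-numbered libraries of different genotypes correlated at between -0.106 and 0.255, so these correlations alone do not show pairing. Transcripts of the Y chromosome set the 3 libraries of tKO replicate 1 apart from those of tKO replicate 2. For this reason the tKO numbers were taken to pair the libraries.

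The fit was tested on simulated data with 200 genes changed. Each of the 10354 and 9884 genes was given its mean over all libraries and normal noise of its fitted spread. Libraries were simulated as independent, so the shares recovered do not allow for an origin shared within a series. At a log2 fold change of 2, 98% of changed genes were recovered for tKO minus WT over the doses, 58% for the difference of the TGF-b effect and 100% for DMOG. At a log2 fold change of 1, the shares were 83%, 4% and 96%. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.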

Results

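RNA sequencing was compared in 18 libraries of day 4 CD4+ T cell cultures. Experiment 1 asked how loss of the 3 PHD proteins in T cells alters gene expression without TGF-b and at 0.2 and 2 ng/ml TGF-b, the cytokine that induces regulatory T cells from naive CD4+ T cells. Experiment 2 asked what DMOG, which inhibits the same enzymes, does at 2 ng/ml TGF-b. Values are mean FPKM ± SD, with n = 2 libraries per group in experiment 1 and n = 3 per group in experiment 2. Where the 3 doses of a genotype are pooled, n = 6 libraries. These come from 2 labelled series, so they may not be independent, and their SD includes effects of dose. Adjusted p-values over the doses treat the libraries as independent and may overstate the certainty. Fold changes are log2 values of FPKM + 1, given ± SE. The FPKM sums of the libraries ran from 548974 to 856147 in experiment 1 and from 386382 to 443888 in experiment 2. Libraries of a group correlated at r between 0.960 and 0.983 across genes in experiment 1, and each library of experiment 2 at 0.991 to 0.996 with the others of its group.

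The targeted genes were read first. Egln1 (chromosome 8, 127432473 to 127473232) had 108 ± 11.5 and 30.4 ± 9.07 FPKM in tKO and WT over the doses. Its libraries ran from 92.8 to 122 FPKM in tKO and from 20.4 to 44.3 in WT, a log2 fold change of 1.84 ± 0.11 (adjusted p = 3.43e-08). Egln3 (chromosome 12, 55279003 to 55304867) ran from 77.4 to 140.2 FPKM in tKO and from 5.68 to 18.7 in WT, with a log2 fold change of 3.13 ± 0.13 (adjusted p = 3.30e-09). Egln2 (chromosome 7, 27943650 to 27951821) fell in tKO from 45.1 ± 4.97 to 29.2 ± 7.29 FPKM, with a log2 fold change of -0.64 ± 0.15 (adjusted p = 0.00572), and ran from 19.9 to 39.0 in tKO and from 35.6 to 48.8 in WT. Floxed alleles lose only some exons, and a single FPKM per gene does not show whether these were read, so the values do not test the deletion. With DMOG, where no allele is floxed, Egln1 had 56.9 ± 6.90 and 16.9 ± 2.14 FPKM in DMOG and vehicle, Egln3 321 ± 15.9 and 5.74 ± 1.11 FPKM and Egln2 12.6 ± 0.441 and 14.5 ± 1.13 FPKM. The DMOG log2 fold changes were 1.69 ± 0.12, 5.59 ± 0.12 and -0.19 ± 0.11 (adjusted p = 2.94e-09, 6.70e-16 and 0.148). Vhl, which encodes the subunit of the ubiquitin ligase that recognises hydroxylated HIF, rose in tKO by 1.22 ± 0.11 (adjusted p = 2.89e-06) and with DMOG by 0.33 ± 0.11 (adjusted p = 0.0148; the call was lost without vehicle replicate 3). Hif1a did not pass in tKO (-0.38 ± 0.22, adjusted p = 0.232) and rose with DMOG by 0.83 ± 0.11 (adjusted p = 5.15e-06).

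**Figure D1:**
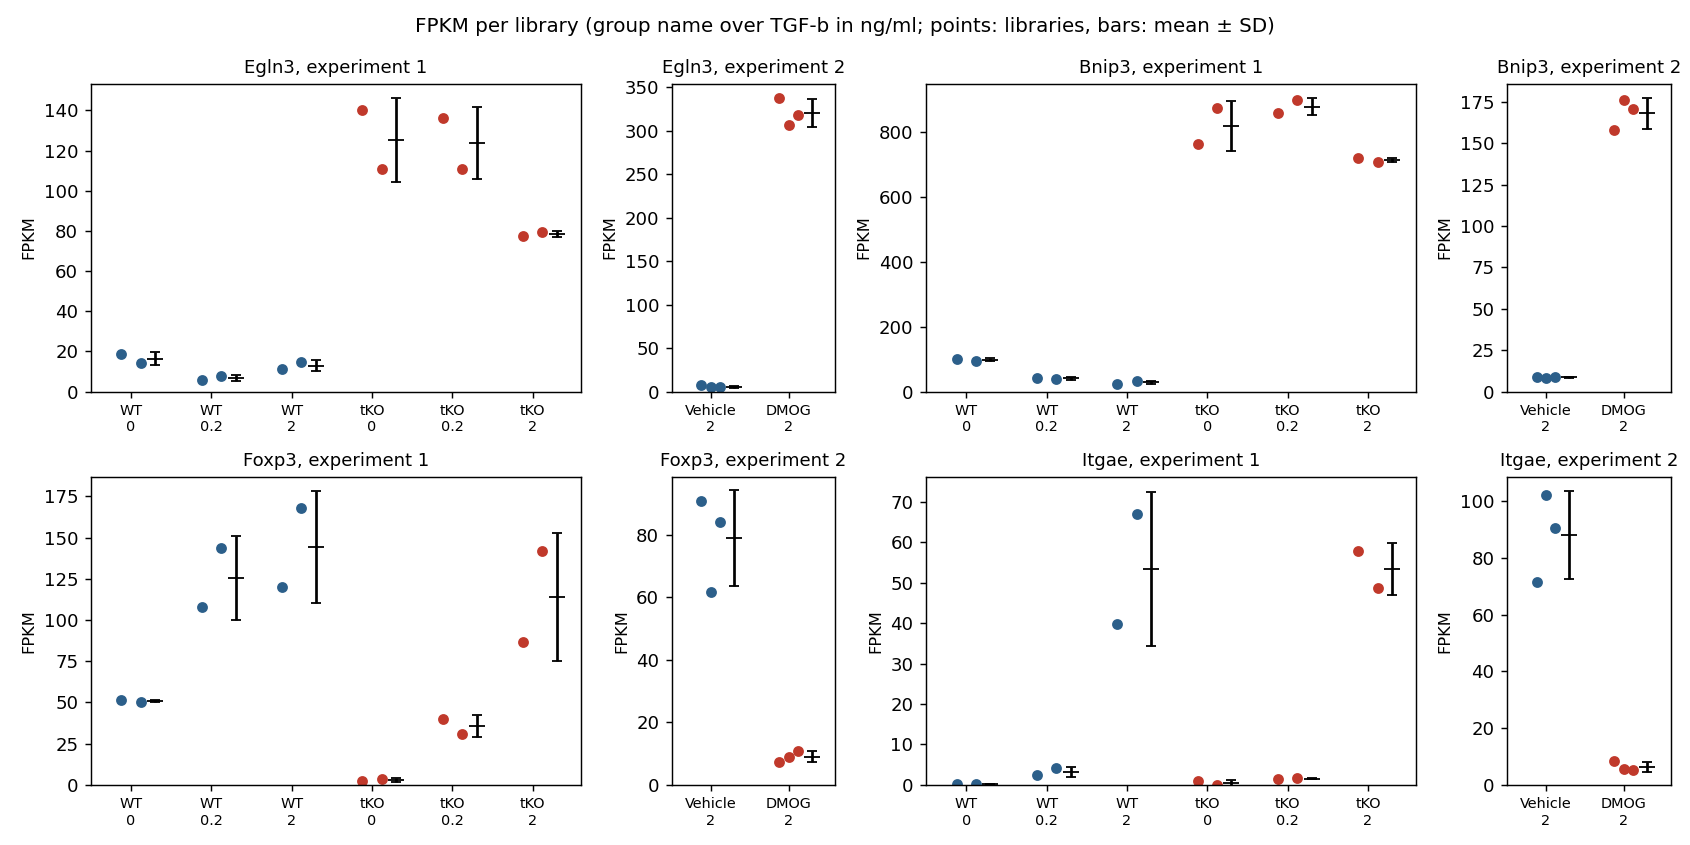
FPKM of Egln3, Bnip3, Foxp3 and Itgae in each library (points), with the mean ± SD of each group (bars), for experiment 1 and experiment 2 on separate axes that start at 0. Foxp3 averages 51.0 FPKM in WT and 2.88 in tKO without TGF-b, 144 and 114 at 2 ng/ml, and 78.9 with vehicle and 8.97 with DMOG.

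Genes of glycolysis and hypoxia were higher in tKO at every dose. Averaged over doses, Bnip3, a mitophagy receptor, had 805 ± 83.2 and 55.5 ± 33.7 FPKM in tKO and WT (log2 fold change 4.03 ± 0.10, adjusted p = 1.01e-11). Mgarp, a mitochondrial protein with 1 WT library listed at 0, had a log2 fold change of 5.93 ± 0.14 (adjusted p = 1.01e-11). The glucose transporter gene Slc2a1 rose from 40.4 ± 22.8 to 169 ± 21.3 FPKM, and the hexokinase gene Hk2 from 4.41 ± 3.30 to 34.2 ± 9.97. Over the doses 2817 of 10354 genes were called, 1440 higher and 1377 lower in tKO, with 554 higher and 275 lower by at least 1 log2 unit. With quantile normalization more were lower, 1398 higher and 1656 lower. With the mean per labelled series, 2 against 2, 1840 genes were called, 1030 higher and 810 lower. A random series factor gave 2273. At all 3 doses, 307 genes were called higher and 120 lower. The count over the doses was 1515 without series WT1 and 1303 without series WT2. The 3 libraries of tKO replicate 1 carried transcripts of the Y chromosome, which the other libraries of experiment 1 lacked or held at trace level, and 77.7% of the calls stayed in the same direction without them.

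Of the 22 glycolysis genes, 20 rose over the doses, 0 fell and 2 did not pass, and adjusted over the list alone 20 rose and 1 fell. Tpi1 (2.22 ± 0.09), Pgk1 (1.98 ± 0.09) and the lactate exporter Slc16a3 (3.13 ± 0.15) had the smallest p with Hk2 (2.86 ± 0.15). Of 28 tested other HIF targets 25 rose and 1 fell, with the same numbers adjusted over the list alone. They included the collagen prolyl hydroxylase gene P4ha2 (4.47 ± 0.19), Ero1l (2.68 ± 0.11), which oxidises proteins in the endoplasmic reticulum, and the secreted glycoprotein gene Stc2 (3.89 ± 0.17, with 1 WT library listed at 0). Both list tests held (camera adjusted p = 2.35e-20 and 1.25e-24, and adjusted p = 0.00986 and 0.00180 with an estimated correlation). Of 20 TCA cycle genes 1 fell, as adjusted over the list alone, and of 35 oxidative phosphorylation genes 0 passed by limma, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05. Camera did not call the list over the doses (adjusted p = 0.604), but called it lower with quantile normalization (0.0151). At 2 ng/ml 9 of the 35 fell (12 adjusted over the list alone; camera adjusted p = 1.98e-06, adjusted p = 0.380 with an estimated correlation). At 0.2 ng/ml 0 passed by limma, 13 at an unadjusted p under 0.05, and camera called the list higher (adjusted p = 0.0167), but not with an estimated correlation (0.546) or with quantile normalization (0.827). At single doses, 15 of 22 glycolysis genes rose without TGF-b, 17 at 0.2 and 20 at 2 ng/ml, and adjusted over the list alone 18, 18 and 21.

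Outside these lists, Il9, a cytokine of mast cell growth, was among the largest rises over the doses. It was listed at 0 to 2.67 FPKM in WT libraries and ran from 88.6 to 820.1 in tKO. Mt1 and Mt2, which bind metals, rose by 4.96 ± 0.15 and 4.94 ± 0.28. Csf2, which encodes GM-CSF, rose by 4.65 ± 0.23 and the chemokine gene Ccl1 by 4.52 ± 0.23. Atf3, a stress-induced transcription factor, rose by 5.29 ± 0.29. The 8 genes with the largest falls were Adh1 (-3.76 ± 0.25), Ccdc164 (listed at 0 in both tKO libraries without TGF-b), Nacc2 (-3.25 ± 0.24), Klf2 (-3.23 ± 0.14), Arl5c (-3.11 ± 0.14), Hsd11b1 (-2.70 ± 0.19), the joint entry Capn3,Ganc and Bambi-ps1 (-2.61 ± 0.23). Atf3 and Adh1 had libraries listed at 0 on their lower side, so their fold changes are uncertain. Klf2 is a transcription factor of quiescent and circulating T cells. Adjusted p-values of the 8 largest rises, Mgarp among them, and the 8 largest falls lay between 1.01e-11 for Mgarp and 2.28e-06 for Bambi-ps1. Not all of the rises are named here.

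Over the doses, Th1 and Th2 genes were also higher in tKO. Of 14 tested Th1 genes 9 rose, 1 fell and 4 did not pass (10 and 1 adjusted over the list alone). The Th1 master regulator Tbx21 ran from 15.6 to 61.2 FPKM in tKO and was listed at 0 to 20.7 in WT (adjusted p = 1.84e-07). Ifng, the main Th1 cytokine, ran from 2.30 to 32.6 in tKO and was listed at 0 to 2.47 in WT (adjusted p = 3.85e-05). Ccl3 rose by 3.00 ± 0.23 and Il12rb2 by 2.75 ± 0.25. The Th1 list test gave an adjusted p of 1.12e-06, and adjusted p = 0.0935 with an estimated correlation. Of 8 tested Th2 genes 7 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 7.50e-06, adjusted p = 0.0269 with an estimated correlation). The Th2 regulator Gata3 rose by 1.28 ± 0.11 and the chemokine receptor gene Ccr4 by 1.60 ± 0.15. Of 8 tested cytotoxic genes 3 rose and 1 fell, with the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.325); without TGF-b 1 rose and 2 fell. Fasl rose by 2.36 ± 0.29, and Ctsw, a protease of cytotoxic cells, had -0.69 ± 0.11.

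Genes of naive and circulating T cells were lower in tKO. Of 13 naive and memory genes 6 fell, 2 rose and 5 did not pass (6 and 3 adjusted over the list alone). S1pr1, the receptor for exit from lymph nodes, fell by 1.99 ± 0.11 on the log2 scale, and the transcription factor gene Tcf7 had -1.65 ± 0.11. The list test gave an adjusted p of 0.00151, and adjusted p = 0.135 with an estimated correlation. Of 11 T cell markers 6 fell and 1 rose (8 and 1 adjusted over the list alone), among them Cd3d (-0.58 ± 0.10), Cd3e (-0.51 ± 0.09) and Cd4 (-0.55 ± 0.10), with a camera adjusted p of 0.00324 and adjusted p = 0.135 with an estimated correlation. Of 7 tested B cell markers 0 passed in tKO by limma, 0 at an unadjusted p under 0.05.

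Foxp3 (chromosome X, 7134467 to 7182546), the regulator of regulatory T cells, differed most without TGF-b. Its libraries were at 1.99 and 3.77 FPKM in tKO and 51.4 and 50.5 in WT without TGF-b, a log2 fold change of -3.78 ± 0.28 (adjusted p = 2.42e-06). At 0.2 ng/ml the means were 35.6 ± 6.57 and 126 ± 25.5 FPKM in tKO and WT (-1.79 ± 0.28, adjusted p = 0.000807). At 2 ng/ml they were 114 ± 38.9 and 144 ± 33.8 FPKM (-0.36 ± 0.28, adjusted p = 0.434), which did not pass. Over the doses, of 18 tested regulatory T cell genes 7 rose and 5 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.190). Tnfrsf9 (1.80 ± 0.12), Ccr8 (1.37 ± 0.11) and Ebi3 (1.93 ± 0.18) rose, so over the doses the members moved both ways. At 2 ng/ml 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.000305, adjusted p = 0.148 with an estimated correlation).

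Th2 cytokines were high in tKO without TGF-b. Il4 was at 37.9 and 56.4 FPKM in tKO libraries and 0.337 and 0 in WT. Il5 was at 62.4 and 48.9 in tKO and listed at 0 in both WT libraries, and Il24 was at 104 and 129.5 and 0.152 and 0. Of 8 tested Th2 genes 6 rose at this dose, as adjusted over the list alone (camera adjusted p = 2.27e-09, adjusted p = 0.0105 with an estimated correlation). At 2 ng/ml 3 Th2 genes rose and 1 fell, as adjusted over the list alone, and the list was not called (camera adjusted p = 0.0555); Il4 was at 0.254 and 0 in tKO and 0 and 0.915 in WT. Of 20 tested cholesterol synthesis genes 6 fell in tKO without TGF-b (9 adjusted over the list alone; camera adjusted p = 2.72e-05, adjusted p = 0.0480 with an estimated correlation), and at 2 ng/ml 5 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00170, adjusted p = 0.131 with an estimated correlation). Other genes with the smallest p without TGF-b were Mt1, Klf2 (-4.37 ± 0.24), Igfbp4 (-3.08 ± 0.18), which binds insulin-like growth factors, and Akr1c18 (4.16 ± 0.24), a steroid dehydrogenase. In all, 998 genes were called without TGF-b, 553 higher and 445 lower in tKO. The count was 513 without WT replicate 1, 523 without WT replicate 2 and 523 without tKO replicate 2 of this dose.

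At 0.2 ng/ml, 1604 genes were called, 943 higher and 661 lower in tKO (881 and 866 with quantile normalization), and the genes with the smallest p were Bnip3 (4.41 ± 0.17), Mgarp, Mt1, Anxa2 (3.40 ± 0.17), Egln3 and the joint entry of Serpina3f and Serpina3g. Anxa2 encodes a calcium-dependent membrane-binding protein. The count was 803 without WT replicate 1, 749 without WT replicate 2, 2667 without tKO replicate 1 and 889 without tKO replicate 2 of this dose. The last is the library with the fewest reads per FPKM, and it lay apart from the others on the third principal component. At 2 ng/ml, 1655 genes were called, 810 higher and 845 lower, and Mgarp, Bnip3 (4.64 ± 0.17), Anxa2 (3.99 ± 0.17), Tpi1 (2.73 ± 0.16) and Ero1l (3.10 ± 0.19) were among the genes with the smallest p. Without WT replicate 1 or 2 of this dose the count was 1057 or 844, and without tKO replicate 1 or 2 it was 736 or 717.

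TGF-b at 2 ng/ml in WT raised TGF-b response genes and lowered glycolysis and cell growth genes. Itgae, which encodes the integrin CD103, had 53.4 ± 19.1 and 0.103 ± 0.0460 FPKM at 2 and 0 ng/ml (log2 fold change 5.58 ± 0.36, adjusted p = 1.22e-06). Ldlrad4, an inhibitor of TGF-b signalling, rose by 5.03 ± 0.24, the transcription factor gene Sox4 by 4.65 ± 0.30 and Smad7, a feedback inhibitor, by 2.27 ± 0.28. Granzyme B, Gzmb, was at 336 and 231 FPKM without TGF-b and listed at 2.14 and 0 with it. Tbx21 was at 20.7 and 6.22 without TGF-b and listed at 0 in both libraries at 2 ng/ml.

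In WT 1626 genes were called at 2 against 0 ng/ml, 807 higher and 819 lower (862 and 830 with quantile normalization). Ctsw (4.30 ± 0.19), the chemokine gene Xcl1 (4.09 ± 0.64), Spp1 (3.87 ± 0.42), which encodes osteopontin, the stress gene Nupr1 (3.81 ± 0.34) and Spsb1 (3.79 ± 0.34) also rose. The interferon-induced gene Ifitm3 had -5.35 ± 0.35, the transglutaminase gene Tgm2 -3.86 ± 0.37, Mgarp -3.35 ± 0.23 and Dnahc7a -3.30 ± 0.55, and Tg, the thyroglobulin gene, and the joint entry Ly6a,Ly6c1 also fell; Tgm2, Mgarp and Dnahc7a had 1 library listed at 0 at 2 ng/ml. The count was 660 without WT at 0 ng/ml replicate 1, 731 without replicate 2 of that group, and 738 without WT at 2 ng/ml replicate 2. At 0.2 ng/ml 165 genes were called in WT, 95 higher and 70 lower, among them Ctsw (2.79 ± 0.19), Ldlrad4 (3.09 ± 0.24) and Lgals3 (1.88 ± 0.17). In order of replicates 1 and 2 that count was 31 and 74 without a WT library at 0 ng/ml, 62 and 45 without a WT library at 0.2, and 100 and 100 without a tKO library at 2 ng/ml, which adds only to the shared spread.

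Of 11 tested TGF-b response genes 10 rose in WT at 2 ng/ml, as adjusted over the list alone (camera adjusted p = 8.59e-14, adjusted p = 0.00417 with an estimated correlation). Of 22 glycolysis genes 19 fell (20 adjusted over the list alone), among them Tpi1 (-1.78 ± 0.16) and Pgk1 (-1.32 ± 0.15), with a camera adjusted p of 2.19e-14 and adjusted p = 0.0157 with an estimated correlation. Of 28 other HIF targets 12 fell and 1 rose (13 and 2 adjusted over the list alone), among them Stc2 (-3.29 ± 0.29, with 1 library listed at 0 at 2 ng/ml) and Bnip3 (-1.79 ± 0.17), with adjusted p = 3.56e-05 and adjusted p = 0.0347 with an estimated correlation. Of 14 Th1 genes 9 fell and 2 rose (9 and 3 adjusted over the list alone), with an adjusted p of 0.000713, and adjusted p = 0.207 with an estimated correlation. Ccl5, a chemokine gene, had -3.05 ± 0.37 and the receptor gene Il12rb1 -2.12 ± 0.32. Of 5 tested Th17 genes 3 rose (4 adjusted over the list alone), Ccr6 by 2.49 ± 0.35 and Rora by 1.41 ± 0.28 among them (camera adjusted p = 0.00150, adjusted p = 0.0485 with an estimated correlation). Of 18 regulatory T cell genes 6 rose and 5 fell, and 6 of each adjusted over the list alone (camera adjusted p = 0.851). Ccr8 rose by 2.48 ± 0.19 and Ikzf4 by 1.92 ± 0.22, and Tnfrsf18, which encodes GITR, had -1.53 ± 0.17. Foxp3 had 144 ± 33.8 and 51.0 ± 0.60 FPKM at 2 and 0 ng/ml (1.46 ± 0.28, adjusted p = 0.00376), and the call was lost without WT at 2 ng/ml replicate 2.

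Cell growth genes fell with TGF-b in WT. Of 27 cell cycle genes 15 fell, as adjusted over the list alone (camera adjusted p = 2.93e-08, adjusted p = 0.0485 with an estimated correlation), Plk1 (-0.86 ± 0.15), Aurkb (-0.90 ± 0.17) and Cdc20 (-0.80 ± 0.15) among them. Of 16 ribosome biogenesis genes 10 fell (14 adjusted over the list alone), such as Nop56 (-0.95 ± 0.14) and Nop58 (-0.86 ± 0.16), with a camera adjusted p of 1.85e-07 and adjusted p = 0.0118 with an estimated correlation. Of 20 cholesterol synthesis genes 9 fell (12 adjusted over the list alone), such as Fdps (-0.96 ± 0.16), with a camera adjusted p of 1.01e-05 and adjusted p = 0.0347 with an estimated correlation. Mki67, a proliferation marker, did not pass (0.10 ± 0.19, adjusted p = 0.780).

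In tKO, TGF-b at 2 ng/ml also raised Itgae, with 53.3 ± 6.43 and 0.490 ± 0.678 FPKM at 2 and 0 ng/ml (5.26 ± 0.36, adjusted p = 1.97e-06). Foxp3 had 114 ± 38.9 and 2.88 ± 1.26 FPKM (4.89 ± 0.28, adjusted p = 4.85e-07). Atp1b1 (4.42 ± 0.27), Ldlrad4 (4.24 ± 0.24), the chemokine receptor gene Cxcr6 (4.08 ± 0.43), Ctsw (4.04 ± 0.19), Xcl1 (3.89 ± 0.64) and Olfm2 (3.82 ± 0.36) rose as well. Among genes with values above 0 in all 4 libraries, the largest falls were in Il24 (-5.53 ± 0.41), Pde1a (-5.36 ± 0.35), a phosphodiesterase, Batf3 (-5.04 ± 0.36), the joint entry Gp49a,Lilrb4 and Gzmb (-4.30 ± 0.55). Il4 went from 37.9 and 56.4 FPKM to 0.254 and 0, and Il5 from 62.4 and 48.9 to 2.87 and 0. In all 1867 genes were called, 786 higher and 1081 lower. The excess of falls depends on the scaling, with 663 higher and 1231 lower after median centring and 843 higher and 800 lower with quantile normalization. The count was 725 without tKO at 2 ng/ml replicate 1, 582 without replicate 2 of that group and 579 without tKO at 0 ng/ml replicate 2. At 0.2 ng/ml 257 genes were called, 176 higher and 81 lower, with Ctsw (3.09 ± 0.19), Timp2 (2.30 ± 0.19), Il24 (-4.73 ± 0.41) and Foxp3 (3.26 ± 0.28) among the smallest p. In order of replicates 1 and 2 that count was 108 and 121 without a tKO library at 0 ng/ml, 708 and 163 at 0.2, and 163 and 163 at 2. With a replicate block within genotype it was 413.

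Of 11 TGF-b response genes 8 rose in tKO at 2 ng/ml (10 adjusted over the list alone; camera adjusted p = 2.76e-10, adjusted p = 0.00965 with an estimated correlation). Of 5 Th17 genes 4 rose (5 adjusted over the list alone; adjusted p = 1.63e-05, adjusted p = 0.0235 with an estimated correlation), Rora by 2.37 ± 0.28 and Ccr6 by 2.96 ± 0.35. Of 16 ribosome biogenesis genes 10 fell (12 adjusted over the list alone; adjusted p = 1.91e-06, adjusted p = 0.0169 with an estimated correlation). Of 18 regulatory T cell genes 9 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 4.92e-05, adjusted p = 0.138 with an estimated correlation), with Nt5e, which encodes the ectonucleotidase CD73, at 3.66 ± 0.34 and Lrrc32, which presents latent TGF-b, at 2.43 ± 0.32. Of 35 oxidative phosphorylation genes 23 fell and 12 did not pass (29 adjusted over the list alone), such as Uqcrq (-1.56 ± 0.25), with a camera adjusted p of 1.46e-10 and adjusted p = 0.338 with an estimated correlation. Of 22 glycolysis genes 2 fell and 20 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.172).

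The TGF-b effects of the genotypes share no library and were set side by side. Both come from a single fit that gives each gene a shared spread. Their calls are therefore not fully independent even where no effect is shared, and the numbers for independent calls may be too low. Of 807 genes called higher in WT, 345 were called higher and 9 lower in tKO, against 61.3 called higher in both if the calls were independent, and 86.2% had the same sign. Their median log2 fold change was 1.23 in WT and 0.67 in tKO. Of 819 genes called lower in WT, 265 were called lower and 19 higher in tKO, against 85.5 for independent calls. The genes of the first comparison were selected in WT, which alone makes the WT median the larger: of 786 genes called higher in tKO the medians were 1.23 in tKO and 0.72 in WT.

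The difference of the TGF-b effect between the genotypes was tested itself, and 308 genes passed, 160 with a higher and 148 with a lower value in tKO. Foxp3 rose with TGF-b by 3.42 ± 0.40 more log2 units in tKO than in WT (adjusted p = 0.00123), and the call was lost without series WT1 or without series WT2. Mgarp had 3.25 ± 0.33, as it fell in WT and had 200 ± 5.77 and 188 ± 12.3 FPKM in tKO at 0 and 2 ng/ml, and Bnip3 had 1.59 ± 0.23 (adjusted p = 0.00382). Il24 (-5.46 ± 0.57) and Casp6, an effector caspase (-2.63 ± 0.30), had negative values, as did Il4 and Pde1a; Il24, Il4 and Mgarp had WT libraries listed at 0, and Pde1a was listed at 0 in both WT libraries at 2 ng/ml. Of 22 glycolysis genes 6 had higher values by this test, and 17 adjusted over the list alone (camera adjusted p = 2.12e-12, adjusted p = 0.0228 with an estimated correlation). Of 8 Th2 genes 4 had lower values (6 adjusted over the list alone; adjusted p = 1.96e-06, adjusted p = 0.0228 with an estimated correlation). Of 20 cholesterol synthesis genes 4 had higher values (15 adjusted over the list alone; adjusted p = 5.23e-10, adjusted p = 0.0228 with an estimated correlation). Itgae did not pass (-0.32 ± 0.51, adjusted p = 0.778). Il4 and Il24, both on the Th2 list, were already near 0 in WT without TGF-b, so they could hardly fall there. The count of 308 rests on few libraries: in order of replicates 1 and 2 it was 78 and 148 without a WT library at 0 ng/ml, 174 and 176 at 0.2, 157 and 119 at 2, 713 and 719 without a tKO library at 0.2, 82 and 86 at 2, and 96 without tKO replicate 2 at 0 ng/ml. Without a whole series it was 9 (WT1), 11 (WT2), 630 (tKO1) and 61 (tKO2), and with a replicate block within genotype 686.

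DMOG at 2 ng/ml TGF-b raised Tbx21, Ifng and Il9 and lowered Foxp3 and Itgae. Foxp3 had 8.97 ± 1.84 and 78.9 ± 15.4 FPKM in DMOG and vehicle (-3.00 ± 0.15, adjusted p = 2.27e-11), and Itgae had 6.40 ± 1.76 and 88.2 ± 15.5 FPKM (-3.60 ± 0.16, adjusted p = 2.75e-12). Tbx21 had 54.7 ± 2.04 and 0.145 ± 0.0555 FPKM (5.60 ± 0.10, adjusted p = 5.94e-17) and Ifng 41.0 ± 5.28 and 0.107 ± 0.0339 FPKM (5.24 ± 0.11). Il9 had the largest rise, with 669 ± 136 and 0.353 ± 0.0456 FPKM (8.93 ± 0.13). In all 6014 of 9884 genes were called, 2735 higher and 3279 lower, with 591 and 807 by at least 1 log2 unit. The balance turned with the scaling, with 3443 higher and 2900 lower after median centring and 3213 higher and 3050 lower with quantile normalization. The first principal component held 91.9% of the variance of experiment 2 and separated the DMOG from the vehicle libraries.

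The other largest rises with DMOG were in Ly6a (7.73 ± 0.13), a surface protein of activated T cells, AA467197 (6.94 ± 0.12), the cytokine gene Il3 (6.51 ± 0.12), the chemokine gene Ccl3 (6.13 ± 0.11), Atf3 (6.08 ± 0.11), Gzmb (111, 73.9 and 53.8 FPKM with DMOG and 0.913, 0.0803 and 0.0440 with vehicle) and Mt2 (5.75 ± 0.13). Among the largest falls were those in Cxcr5 (-5.27 ± 0.12), the homing receptor to B cell follicles, Cd72 (-4.95 ± 0.12), Sox4 (-4.94 ± 0.11), Cd101 (-4.87 ± 0.13), Nsg2 (-4.76 ± 0.11), Pik3ip1 (-4.72 ± 0.11), a brake on PI3 kinase, and Pou2af1 (-4.47 ± 0.10). These genes had adjusted p-values between 7.54e-18 for Il9 and 5.60e-13 for Gzmb.

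Of 22 glycolysis genes 19 rose with DMOG and 3 did not pass, with 19 adjusted over the list alone. Hk2 (4.20 ± 0.11), Pgk1 (3.10 ± 0.11) and Eno1 (2.85 ± 0.10) had the smallest p. Of 27 tested other HIF targets 23 rose and 3 fell, as adjusted over the list alone, with Bnip3 at 4.15 ± 0.11 and Ak4 at 3.70 ± 0.10. Of 14 Th1 genes 11 rose and 3 fell, and of 12 TGF-b response genes 2 rose and 8 fell (2 and 9 adjusted over the list alone). Smad7 had -1.35 ± 0.13, and Skil did not pass (-0.01 ± 0.12, adjusted p = 0.942). Of 19 regulatory T cell genes 9 rose and 9 fell, with falls in Nt5e (-3.01 ± 0.14), Nrp1 (-2.54 ± 0.15) and Lrrc32 (-2.12 ± 0.13). Of 13 naive and memory genes 10 fell and 1 rose, with Klf2 at -3.60 ± 0.15, and of 6 tested Th17 genes 4 fell and 1 rose, with Ccr6 at -3.52 ± 0.16. All 11 T cell markers fell, Thy1 by 1.71 ± 0.12 and Cd3e by 1.39 ± 0.12 on the log2 scale. Counts adjusted over the list alone were the same for the Th1, regulatory T cell, naive and memory, Th17 and T cell marker lists. Camera called 14 lists in this comparison, and 0 with an estimated correlation: adjusted p = 0.210 with an estimated correlation for glycolysis, 0.424 for other HIF targets and Th1, 0.533 for TGF-b response and Th17, 0.50 for naive and memory genes, and 0.449 for T cell markers.

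**Figure D2:**
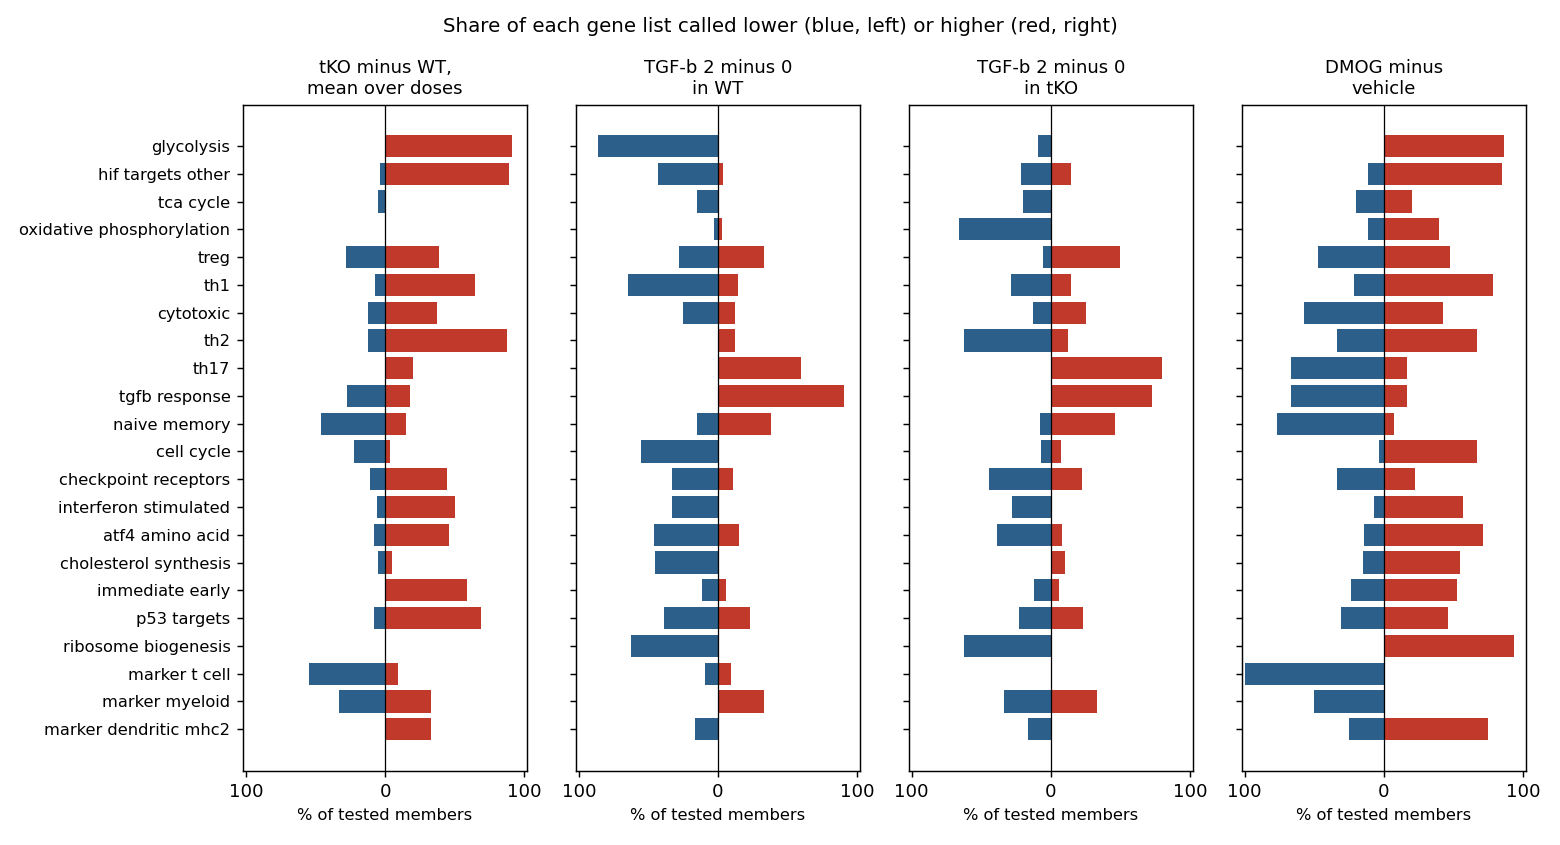
Share of the tested members of each gene list with at least 3 tested members in both experiments called higher (red, to the right) or lower (blue, to the left), in percent, in 4 comparisons. Of 22 glycolysis genes 20 were higher in tKO and 19 higher with DMOG, and 19 were lower with TGF-b in WT.

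Many of the same genes were called in the same direction in tKO and with DMOG at the same TGF-b dose. Of 9192 genes tested in both experiments, 709 were called higher in tKO at 2 ng/ml and 2533 with DMOG, and 572 were called higher in both, against 195 for independent calls. Likewise 506 were lower in both, against 251, and 66 were called in opposite directions. Log2 fold changes correlated across genes at Pearson's r = 0.638 and Spearman's rho = 0.498, and 65.9% had the same sign. Genes are not independent replicates, so r carries no p, and the planned Fisher's exact tests of the overlaps (p = 3.71e-209 higher and 3.51e-86 lower) overstate the certainty. When libraries were regrouped within each experiment, 4 of 30 splits, the real one included, gave an r as large. The others of these kept WT apart from tKO and most vehicle libraries together. They still carry much of the real effect, so the count cannot decide on chance. Splits that mixed WT and tKO gave r between -0.141 and 0.113. The 10 genes with the largest change in both were Il9, Scin (4.53 ± 0.11 with DMOG), which encodes an actin-severing protein, Tbx21, Upp1 (4.58 ± 0.14), a uridine phosphorylase, Atf3, P4ha2 (4.25 ± 0.18), Mgarp (4.21 ± 0.11), Bnip3, AA467197 and Anxa2 (4.37 ± 0.11). Cpm (1.45 ± 0.35 in tKO and -1.38 ± 0.12 with DMOG), P2rx7 (1.78 ± 0.34 and -1.16 ± 0.11) and Il1r2 (1.14 ± 0.30 and -2.23 ± 0.11) were called in opposite directions, though in tKO the calls of Cpm and Il1r2 were lost without any 1 of the 4 libraries at 2 ng/ml and that of P2rx7 without tKO replicate 2. Foxp3 had -0.36 ± 0.28 in tKO at 2 ng/ml and -3.00 ± 0.15 with DMOG, and Itgae 0.04 ± 0.36 and -3.60 ± 0.16. The tables were normalized separately and the differences between tKO and DMOG were not tested.

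**Figure D3:**
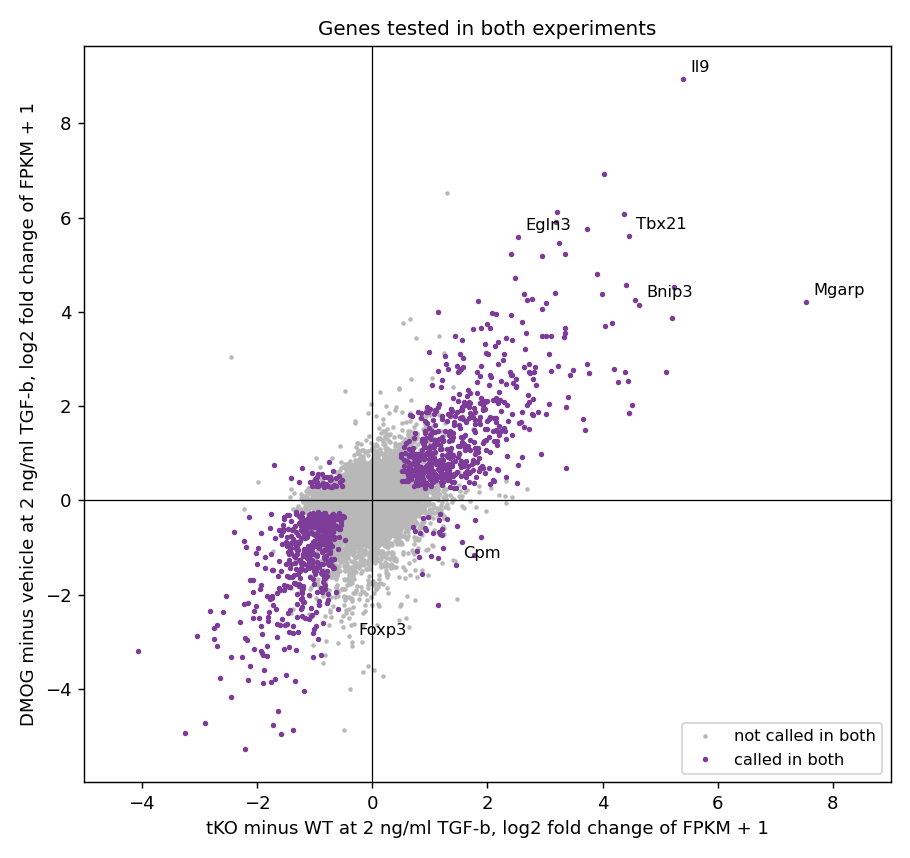
Log2 fold changes of FPKM + 1 for tKO minus WT at 2 ng/ml TGF-b (horizontal) and DMOG minus vehicle (vertical), 1 point per gene tested in both experiments, with genes called in both in purple. Of these, 572 lie at the upper right, 506 at the lower left and 66 in the other quadrants, and 1 gene lies beyond the horizontal axis.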

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

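The tests of explanations in this part were chosen after the results were seen. The difference of the TGF-b effect (2 minus 0 ng/ml) between tKO and WT passed for 308 genes. The single genes stand out because their response to TGF-b differed between the genotypes by a direct test (limma), with values given as tKO minus WT on the log2 scale. Among the smallest p were those of Il4 (-5.66), Mgarp (3.25), Pde1a (-4.84, with both WT libraries at 2 ng/ml listed at 0, so no measure of size), Il24 (-5.46) and Casp6 (-2.63), of which Il4, Mgarp and Il24 also had libraries listed at 0. Of the fixed panel, Foxp3 (3.42), Pdk1 (1.64) and Bnip3 (1.59) passed, Pdk1 with the call lost without any 1 WT library, without tKO replicate 2 at 0 ng/ml, or without either tKO library at 2 ng/ml. The median difference was 1.08 over glycolysis genes, -2.31 over Th2 genes and 0.84 over cholesterol synthesis genes. Il4 and Il24, both on the Th2 list, were already near 0 in WT without TGF-b and could hardly fall there. Their values therefore mostly reflect the difference between the genotypes without TGF-b. Entries with no gene symbol, which the comparisons did not use, held 37 with higher and 55 with lower values in tKO than in the WT controls among 515 tested. Some regions, such as chromosome 2, 87366301 to 87366769, held more than 1 entry, so these are not counts of distinct loci. The smallest p was at chromosome 1, 24618371 to 24623031, which was listed at 0 in the 4 WT libraries at 0.2 and 2 ng/ml, so no size is given; without TGF-b it was at 774 and 930 FPKM in WT and 603 and 1150 in tKO.

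Libraries of series tKO1 carried transcripts of the Y chromosome. Eif2s3y was at 43.6, 45.5 and 42.0 FPKM in tKO replicate 1 at 0, 0.2 and 2 ng/ml and listed at 0 in tKO replicate 2 and in all WT libraries, and Xist was at or below 0.0531 FPKM in those 3 libraries and at 1.04 or more in the other 9. These genes were chosen after their values were seen. If the sex of the mice were the cause of the 2817 calls between genotypes, most would end without series tKO1, but 77.7% were still called in the same direction. Of 100 splits of the 12 libraries within doses, 1, the real one, called as many genes, and the highest other called 1191, which excludes chance only if the libraries of a series are independent. The Y transcripts speak against that in tKO. With the 4 labelled series as units there are 3 splits, too few for a share under 0.05: 1, the real one, called 2817 genes, and the highest other called 0. With the mean per series 1840 genes were called. A hypothesis that stays open is that most of these calls reflect the lost PHD proteins, and other differences between the 2 mouse lines may add to them.

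Foxp3 was lower in tKO without TGF-b and did not pass at 2 ng/ml, and that difference was itself tested, with the call lost when series WT1 or WT2 was left out. The Y-bearing series could not account for it, as the log2 fold change without series tKO1 was -3.45. Pre-formed regulatory T cells left in the sorted WT cells may also raise Foxp3 without TGF-b; they would bring Ikzf2, which had a log2 fold change of -0.15 at this dose. Ikzf2 was at 0.859 and 0.784 FPKM in WT and 0.243 and 1.18 in tKO, too close to the floor to decide, although the sort for naive cells should remove such cells. A lower induction of Foxp3 in tKO and a carried-over population therefore cannot be told apart here.

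H2-Ab1, an MHC class II gene (chromosome 17, 34400172 to 34406363), had 405 ± 93.1 FPKM in tKO and 91.1 ± 61.4 in WT (SD over 6 libraries), and 38.1 ± 3.58 with DMOG and 1.99 ± 0.939 with vehicle (n = 3). Antigen-presenting cells in the cultures would bring its partner genes, but H2-Aa and H2-Eb1 had a mean log2 fold change of -0.39 in tKO. With DMOG they stayed at 0.321 and 1.07 FPKM, against 1.35 and 1.61 with vehicle. Their mean was 1.93% of the rise of H2-Ab1, but the share that such cells would bring was not measured. This test for DMOG replaced 2 earlier ones after their values were seen; of these, the last, on H2-Eb1 alone, had left the explanation open. Cd74, a class II partner gene with a high baseline, rose with DMOG by 1.07 ± 0.15, and in tKO its means were higher at all 3 doses without passing (0.60 ± 0.23 over the doses, adjusted p = 0.0652). Batf3, a transcription factor of dendritic cells, was at 64.4 and 79.1 FPKM in tKO and 1.35 and 1.42 in WT without TGF-b, at 1.14 and 1.26 in tKO and listed at 0 in both WT libraries at 2 ng/ml, and at 14.9, 17.2 and 13.6 with DMOG and 0, 0 and 0.0583 with vehicle. The rise of Cd74 would go with antigen-presenting cells. In tKO without TGF-b and with DMOG, Batf3 rose without a rise of Itgax, Flt3 or Xcr1. In tKO without TGF-b, Itgax and Flt3 were listed at 0 in both libraries. The joint entry Fyco1,Xcr1 averaged 0.720 FPKM there, against 0.982 in WT. With DMOG, Itgax, Flt3 and Xcr1 averaged 0.0196, 0.0305 and 0.0438 FPKM. Itgax was also listed at 0 in all WT libraries, and a value of 0 can be a failed estimate. These low values therefore cannot exclude dendritic cells as the source of Batf3. The rises of Cd74 and Batf3 have no tested explanation. The values of H2-Aa and H2-Eb1 argue against antigen-presenting cells as the cause of the rise of H2-Ab1. The rise of Cd74 with DMOG goes the other way, so the explanation is not excluded there. Without the Y-bearing series the value for H2-Ab1 was 2.38. Reads shared between class II genes were not tested, and a rise of H2-Ab1 in T cells that lack PHD proteins is a hypothesis that stays open in tKO.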

How the results depend on the processing

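The random series factor for the TGF-b contrasts and the use of a single entry per symbol were chosen after seeing the data. Of 731 gene and comparison pairs called, 388 were called in every alternative, and 0 changed sign with a call; of results for single genes with libraries kept, 372 lost and 306 gained a call, and with libraries left out 1627 lost and 269 gained one. A lone library left in a group is assumed to vary like the other groups, and the cause of a change was not tested unless said. Without 1 library or series, counts ranged from 1303 to 3209 for tKO minus WT over doses, 298 to 1235 at 0, 475 to 2667 at 0.2 and 387 to 2160 at 2 ng/ml; from 158 to 2091 for TGF-b at 2 and 7 to 237 at 0.2 ng/ml in WT; from 360 to 2388 and from 46 to 708 in tKO; from 9 to 719 for the difference of the TGF-b effect; and r from 0.606 to 0.658. The lowest counts came from fits without a whole series, which have fewer samples. With the mean per series, 1840 genes were called over doses. With only the groups compared the counts were 631 for tKO minus WT at 0.2 ng/ml, 81 in WT and 27 in tKO for TGF-b at 0.2 ng/ml, and 511 for the difference. With no filter, 72 genes were called for 0.2 ng/ml in WT and 157 for the difference, and with no variance trend 105 and 167. The correlation was 0.498 as Spearman's rho and 0.724 against the mean over doses. With an estimated correlation the lists called fell from 9 to 3 for genotype, 11 to 3 for TGF-b in tKO and 14 to 0 for DMOG (camera). With quantile normalization 7 lists were higher and 4 lower for genotype, against 7 and 2, and 7 and 5 for TGF-b in tKO, against 5 and 6. For DMOG all counts, leave-outs included, lay within 1.5 times 6014. Depth limits low genes most in tKO at 0.2 ng/ml, replicate 2; without it 87.97% of genotype calls over doses stayed.

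In WT and in experiment 2 the replicate numbers were not shown to pair the libraries: deviations of same-numbered libraries correlated at 0.186, 0.0573 and 0.0899 in WT and at -0.142, -0.194 and 0.443 in experiment 2. With the replicate block 512 genes were called for the difference of the TGF-b effect, and with a replicate block within genotype 283 and 413 for 0.2 ng/ml in WT and tKO and 686 for the difference; a random series factor gave 252 for 0.2 ng/ml in WT and 528 for the difference. Other counts stayed within 1.5 times under the block. For TGF-b in tKO, where the numbers pair the libraries, no call of a named gene was lost under the block.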

Other observations

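The covariance over splits was chosen, and the bounds for the shares of splits were written, after the results were seen. Other gene lists were tested as background to the comparisons above. Of 13 tested p53 targets 9 rose and 1 fell in tKO over the doses, as adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.0910 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.90 ± 0.13 on the log2 scale, and Sesn1 had -2.17 ± 0.13; with DMOG they had 4.26 ± 0.12 and -3.52 ± 0.11. Of 17 immediate early genes 10 rose (10 adjusted over the list alone; adjusted p = 7.50e-06, adjusted p = 0.316 with an estimated correlation), Ier3 by 3.90 ± 0.17 and Irf4 by 1.47 ± 0.11. Of 18 interferon-stimulated genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00324, adjusted p = 0.413 with an estimated correlation), Bst2 by 1.30 ± 0.13 and Isg15 by 1.63 ± 0.21. Of 9 checkpoint receptor genes 4 rose and 1 fell, as adjusted over the list alone, with Cd274, which encodes PD-L1, at 1.60 ± 0.19 and Tigit at 1.03 ± 0.16 (camera adjusted p = 0.157). Of 13 ATF4 and amino acid genes 6 rose and 1 fell, with the same numbers adjusted over the list alone, Sesn2 by 1.60 ± 0.18 (camera adjusted p = 0.157).

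With DMOG, 15 of 16 ribosome biogenesis genes rose and 18 of 27 cell cycle genes rose with 1 fall (15, 19 and 1 adjusted over the list alone; camera adjusted p = 0.00157 and 0.00144, adjusted p = 0.533 with an estimated correlation for both). Nop56 had 0.45 ± 0.11, Aurka 0.88 ± 0.11 and Rrm2 0.78 ± 0.11. Over the doses, 0 of 16 ribosome biogenesis genes passed by limma in tKO, 1 at an unadjusted p under 0.05, and 6 of 27 cell cycle genes fell with 1 rise, as adjusted over the list alone (camera adjusted p = 0.0559). By dose, 5 cell cycle genes fell and 0 rose without TGF-b (8 and 0 adjusted over the list alone; adjusted p = 1.08e-05, adjusted p = 0.113 with an estimated correlation), 4 fell and 0 rose at 0.2 ng/ml, as adjusted over the list alone (0.00398 and 0.267), and 2 rose and 0 fell at 2 ng/ml, with 0 adjusted over the list alone (0.0397 and 0.380). Of markers of other cells over the doses, 1 of 3 myeloid genes rose and 1 fell. The myeloid genes tested were Cd68, Cst3 and Ctss, while Lyz1, Lyz2, S100a8 and S100a9 were listed at 0 in all libraries of experiment 1. The calls are therefore no measure of myeloid cells. Of dendritic and MHC class II genes 2 of 6 rose (H2-Ab1 and Batf3), and 1 of 1 CD8 T cell gene rose. Of 2 erythroid and 1 gamma-delta or NKT gene 0 passed by limma, 0 and 0 at an unadjusted p under 0.05. No NK gene passed the expression filter in either experiment. With DMOG the only B cell gene tested, Cd79b, had -2.11 ± 0.13 and the myeloid gene Itgam -2.95 ± 0.09.

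For DMOG, 10 splits of 6 libraries are too few for a share under 0.05: 1, the real one, called 6014 genes, and the highest other called 0. For the correlation of tKO with DMOG across genes, the statistic planned for the splits was r. It was 0.638, 4 of 30 splits, the real one included, gave a value as large, and the highest other gave 0.706. The other splits with an r as large (0.676, 0.706 and 0.640) kept WT apart from tKO and exchanged 1 vehicle for 1 DMOG library. They still carry much of the real effect, so this count cannot decide on chance. Splits that mixed WT and tKO gave r between -0.141 and 0.113. The covariance was added only after those values of r were seen, because r does not depend on the size of the effects and stays high in splits that keep most libraries of a group together. The covariance was 0.383, 1 of 30 splits, the real one, gave a value as large, and the highest other gave 0.145. As the covariance was picked after the planned statistic did not decide the question, it does not replace that statistic.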
